A study of Homo sapiens with 414 samples.

How the data were processed

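The data are gene counts of single LNCaP cells, transfected with a non-targeting siRNA from Dharmacon (control) or an siRNA against SULT2B1 from IDT (knockdown) and captured on a Fluidigm C1 plate for cells of the large size class. Per the labels' protocols, capture sites with 0 cells or more than 1 cell and cells stained by ethidium homodimer-1, a dye that enters dead cells, were excluded under the microscope, and sequencing was on an Illumina HiSeq2500. That inspection is how doublets were treated; no doublet caller was run. The deposited counts are whole numbers of reads per gene and cell, not normalized, without molecular identifiers. Per the submitters' processing notes, FastQC 0.11.3, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR 3.2.2 were used with genome build GRCh38.p3; the order of these steps, the annotation release and the strand setting of the counting are not given in the sources used here. Amplified reads are not independent molecules, and genes that share sequence (paralogs, pseudogenes, replication-dependent histones) or overlap can lose or swap reads in such counting.

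The table holds 36135 genes as Ensembl identifiers. Of these, 34891 were named through the gene name table provided, 257 through GENCODE 29, and 987 have no name; 484 share a name with another identifier. Coordinates come from GENCODE 29 on GRCh38. The series lists 414 samples. The 401 cells used are those whose label names a column of the table and a single cell. Not used were 4 labelled cells without a matching column, 6 libraries labelled as holding several cells, 1 repeat library of unstated cells and 2 first runs of cells that were sequenced again, and 4 columns of values were not used. The 2 cells sequenced again are knockdown cells of batch 1.

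Cells are not replicates, so counts were summed over the cells of each arm and batch, giving 3 control and 3 knockdown libraries. The fit was the edgeR 4.0.16 quasi-likelihood test (limma 3.58.1, R 4.3.3) with robust dispersions, TMM scaling, filterByExpr with its minimum count of 10, no covariates and Benjamini-Hochberg adjustment over 20326 genes. The common dispersion was 0.497. Log2 fold changes are knockdown over control. An arm with 0 reads was set at 3 counts over the arm, 0.0134 CPM in control and 0.0125 CPM in knockdown, to give a lower limit of the fold; a gene with 1 to 3 reads in an arm has a ratio with an exact conditional counting interval at 95%. The labels' word Batch marks the number that the arms share, so batch pairs the libraries. The correlations of the deviations of same-numbered libraries from their arm's mean were 0.0551, -0.00370 and -0.00190, and the fit with batch as a block is reported wherever it changes a call.

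The design, the alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. The rule names SULT2B1, then the 12 largest rises and the 12 largest falls among genes past an adjusted p of 0.05 with the same direction within all 3 batches and an average of at least 5 CPM (71 higher and 78 lower genes met these conditions), then up to 4 members of each list, called members first. Some genes are not reported here. The lists are interferon response, TNF and NF-kB response, p53 targets, death receptor signalling, BCL2 family and mitochondrial apoptosis, S phase, G2 and M phase, androgen response genes, immediate early and heat shock genes, unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis, LXR targets, steroid and sulfate metabolism, glycolysis and hypoxia, nuclear respiratory chain, mitochondrially encoded genes, ribosomal proteins, RNA interference machinery, ERK targets, nuclear long noncoding RNAs, and luminal, basal, neuroendocrine, mesenchymal and blood or endothelial markers. The 25 lists with at least 3 tested members were tested two-sided with camera at its preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation, which does not assume that members vary independently, and fry, which tests whether members move on balance in 1 direction, were alternatives. Members were also counted as passing when adjusted over the list alone. Medians of lists are of edgeR log2 fold changes; medians within a batch are differences of log2(CPM + 1).

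Per cell, the share of cells with at least 1 read, the mean of log2(CPM + 1) over each list's members, reads, genes with a read and the mitochondrial share were each reduced to 1 value per arm and batch and compared by two-sided exact permutation tests over the 6 values (smallest p 0.1) and within batches (smallest p 0.25). Score tests were adjusted over 25 lists. Shares have exact Clopper-Pearson intervals at 95%. Where 0 cells had a read, the limit given in the text is 3 cells over the number of cells, and the plot shows the exact interval. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Cells were not clustered into types because the labels name 1 cell line.

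Tested on simulated data with counts drawn from the means and sizes of these libraries, with 200 genes changed, the fit recovered 5% of genes changed 2-fold, 43.5% of those changed 4-fold and 45.5% of those changed 8-fold, with 0, 4 and 5 false calls among 19275, 19270 and 19200 genes. For changed genes with at least 5 CPM the recovery was 11.2%, 76.4% and 89.9%. A fold near 2 is therefore mostly missed with 3 libraries per arm.

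Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, batch as a block, leaving out each library or each batch, equal weight per cell with limma (with and without the block), a filter on cells with under 100000 reads or 2000 genes, thinning each cell to 100000 reads, and leaving out the cells sequenced again. Chosen after seeing the data were leaving out cells with over 20% mitochondrial reads, requiring a read in at least 10% of the cells of an arm, and the estimated correlation together with the block or with the first of these.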

Results

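Single-cell RNA sequencing was carried out on LNCaP cells, an androgen-responsive line established from a human prostate carcinoma, after transfection with a non-targeting siRNA (control) or an siRNA against SULT2B1 (knockdown), which came from different suppliers. SULT2B1 encodes a cytosolic sulfotransferase whose isoform b adds sulfate to cholesterol and related sterols. The series is concerned with how this enzyme affects the death of prostate cancer cells in response to TNF. Cells were harvested 48 h after transfection and captured singly on a Fluidigm C1 plate, a microfluidic device whose capture sites are inspected under a microscope. They came in 3 batches that each held both arms. The 401 cells used comprised 209 control cells (76, 66 and 67 in batches 1, 2 and 3) and 192 knockdown cells (66, 65 and 61). Each cell had between 169244 and 2353816 reads in genes, with a median of 1150826. Between 3058 and 11061 genes had a read in a cell, with a median of 8739. Summed over the cells of a batch, the control libraries held 79393642, 73256509 and 77919014 reads and the knockdown libraries 77897029, 71630108 and 84359044. The batch was the replicate (n = 3 summed libraries per arm). The labels name batches without saying that they were separate cultures, so p-values measure the spread between these batches, which may be technical.

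Depth and RNA quality were compared between the arms before any gene. The median number of reads per cell, averaged over batches, was 1105100 ± 53998 in control and 1235000 ± 158890 in knockdown (SD, n = 3; exact permutation test, two-sided, p = 0.3). The median number of genes with a read was 8642 ± 91.2 and 8872 ± 207 (exact p = 0.2). The mean number over cells was 8231 ± 264 and 8598 ± 145 (exact p = 0.1), higher in each knockdown batch than in any control batch. The median mitochondrial share of reads was 6.56% ± 0.672 and 6.58% ± 0.651 (exact p = 1). Cells with over 20% mitochondrial reads, which can be a sign of damage, made up 27.6%, 12.1% and 8.96% of control cells in batches 1, 2 and 3 and 9.09%, 0% and 3.28% of knockdown cells (exact p = 0.2). In all, 35 of 209 control cells and 8 of 192 knockdown cells were above that limit. With 3 against 3 values the exact test cannot give a p below 0.1.

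SULT2B1 transcripts were lower in the knockdown arm in all 3 batches. The gene (ENSG00000088002, chromosome 19, 48552075 to 48599425, plus strand, GENCODE 29 on GRCh38; protein coding) had 152, 109 and 332 reads in the control libraries and 13, 21 and 0 in the knockdown libraries of batches 1, 2 and 3. This was 2.61 ± 1.47 CPM (counts scaled to the size of the library) in control and 0.149 ± 0.142 in knockdown (SD, n = 3), a log2 fold change of -4.13 (SE 1.43). The edgeR quasi-likelihood p was 0.0226 before and 0.268 after Benjamini-Hochberg adjustment over all genes tested, so the transcript did not pass the threshold. DESeq2 gave an adjusted p of 0.0156. The log2 fold change was -5.26 without batch 2 and -2.99 without batch 3. With equal weight per cell the difference of log2(CPM + 1), which understates the change of low genes, was -1.48. Gene counts do not separate isoform b from isoform a.

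Detection per cell followed the same order. A SULT2B1 read was found in 15 of 76, 14 of 66 and 14 of 67 control cells. These are shares of 19.7% (exact 95% Clopper-Pearson interval 11.5 to 30.5), 21.2% (12.1 to 33.0) and 20.9% (11.9 to 32.6). In the knockdown arm it was found in 2 of 66 cells (3.03%, 0.369 to 10.5) and 2 of 65 cells (3.08%, 0.375 to 10.7) of batches 1 and 2. In batch 3 it was found in 0 of 61 cells, which allows a share of up to 4.92%. The mean share was 20.6% ± 0.777 in control and 2.04% ± 1.76 in knockdown (SD, n = 3; exact permutation test, two-sided, p = 0.1). This is the smallest p possible, as is the 0.25 found within batches. With each cell thinned to 100000 reads the shares were 11.2% ± 4.02 and 0.513% ± 0.888. A single cell held 92.3% of the SULT2B1 reads of knockdown batch 1 and 90.5% of those of batch 2. Reads carry no molecular identifiers, so intervals and limits throughout cover counting error only.

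**Figure D1:**
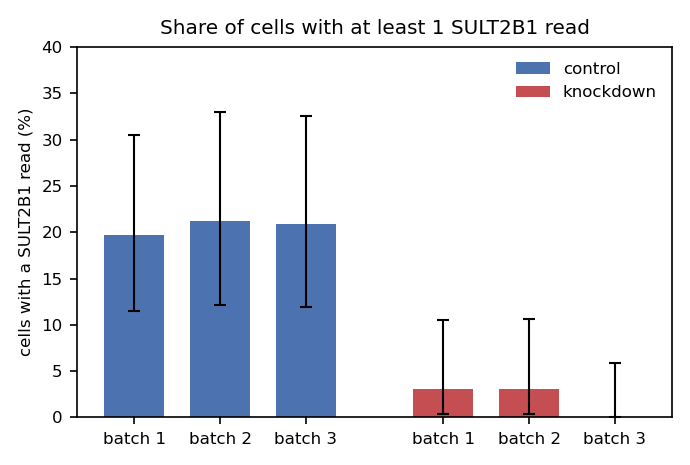
Share of cells with at least 1 SULT2B1 read (%, vertical axis) in each control and knockdown batch, with exact 95% binomial intervals as error bars. The 3 control batches lie between 19.7% and 21.2% and the 3 knockdown batches between 0% and 3.08%.

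The largest rises in knockdown cells were of antiviral and interferon transcripts that were nearly absent from control cells. RSAD2, which encodes the antiviral enzyme viperin, had 0 reads in every control library and 61.3 ± 18.1 CPM in knockdown (at least 4580-fold higher; the limit for 0 reads is 3 counts over the whole arm). IFNB1, which encodes interferon beta, rose to 25.1 ± 4.19 CPM from 0 control reads (at least 1874-fold higher). The chemokine genes CXCL11 (57.6 ± 15.0 CPM, at least 4304-fold higher), CCL5, CXCL10 and CXCL8 rose as well. In the opposite direction, the histone gene H4C3, the histone mRNA-binding gene SLBP, the nucleotide synthesis gene RRM2 and the DNA repair gene BRCA2 were among the largest falls. All values are means ± SD over 3 libraries per arm.

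Of 20326 genes tested with edgeR, 158 passed an adjusted p of 0.05, 80 higher and 78 lower in knockdown, and 2739 passed an unadjusted p of 0.05. With batch as a block, 38 genes passed (26 higher and 12 lower), 37 of them shared with the 158. DESeq2 called 1442 genes (659 higher and 783 lower), 157 of the 158 among them. Leaving out control library 1, 2 or 3 gave 69, 68 and 65 genes, and leaving out knockdown library 1, 2 or 3 gave 46, 48 and 63. All 158 genes kept their direction in each of these fits.

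Among genes averaging at least 5 CPM with the same direction in all 3 batches, the 12 largest rises also included the interferon genes IFNL1 and IFNL2. CCL5, a chemokine that attracts T cells, had 2 control reads and reached 234 ± 166 CPM (ratio 26370, counting interval 7300 to 217750). RAET1L, of the family of ligands for the NKG2D receptor of natural killer cells, had 1 control read and reached 54.9 ± 8.68 CPM (ratio 12288, 2205 to 485403). GBP4, a guanylate-binding protein gene, also had 1 and reached 13.6 ± 11.9 CPM (ratio 3085, 553 to 121886), as did CXCL8, a chemokine for neutrophils, which reached 11.1 ± 15.0 CPM (ratio 2342, 420 to 92522). IFNL2 reached 10.6 ± 4.92 CPM from 0 control reads (at least 795-fold higher). IFNL1 rose by a log2 fold change of 9.67 (SE 1.17) to 40.9 ± 38.0 CPM. OAS2, which makes oligoadenylates on sensing double-stranded RNA, rose by 9.23 (SE 1.30) to 14.4 ± 9.21 CPM. CXCL10, a T cell chemokine, rose by 9.31 (SE 1.43), from 0.970 ± 1.09 to 612 ± 488 CPM. IFIT3, whose protein takes part in binding viral RNA, rose by 9.23 (SE 1.09), from 1.88 ± 1.65 to 1124 ± 233 CPM. The edgeR adjusted p was between 0.000223 for RAET1L and 0.0471 for CXCL8. With the block, RSAD2 (0.0431), CXCL11 (0.0431), CCL5 (0.00352), RAET1L (0.00850), GBP4 (0.0286) and IFNL1 (0.0353) still passed. With it IFNB1 (0.0645), IFIT3 (0.0724), OAS2 (0.0854), CXCL8 (0.0939), IFNL2 (0.111) and CXCL10 (0.182) did not. CXCL8 did not pass without the cells over 20% mitochondrial reads (0.0854) or with equal weight per cell (0.168), nor did CXCL10 (0.172) and IFIT3 (0.0720) without a filter on low counts. Of the 12 rises 6, 6 and 6 passed without control library 1, 2 or 3, and 6, 8 and 7 without knockdown library 1, 2 or 3. Control library 1 held the 5 control reads of OAS2, whose fitted log2 fold change was 13.13 without it, and the single control read of RAET1L, GBP4 and CXCL8. Control library 3 held both control reads of CCL5. Knockdown library 2 held 2102 of the 2504 CXCL8 reads of its arm, and the fitted value of that gene was 10.83, and 8.63 without that library. That of GBP4 was 11.13, and 10.14 without knockdown library 1. IFNL1 was at 10.85 without control library 3 and 8.59 without knockdown library 3. CXCL10 was at 10.66 and 8.71 without control library 2 or 3 and 8.54 without knockdown library 3, and IFIT3 was at 9.93 without control library 2. IFNL2 shares nearly identical sequence with IFNL3, and RAET1L with its family, so reads may be split between these genes.

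Among the 12 largest falls, H4C3, a replication-dependent histone H4 gene, fell from 972 ± 165 to 239 ± 54.4 CPM (log2 -2.03, SE 0.204, edgeR adjusted p = 0.00863). H4 genes are near-copies of each other whose reads may be split. SLBP, which binds the stem-loop of histone mRNAs, fell by 2.02 on the log2 scale (SE 0.224, adjusted p = 0.0114). RRM2, a subunit of ribonucleotide reductase, fell from 191 ± 48.8 to 48.2 ± 13.7 CPM (log2 -1.98, SE 0.270, adjusted p = 0.0251), and BRCA2, a homologous recombination gene, fell by 1.78 (SE 0.212, adjusted p = 0.0153). NCAPG2, a condensin subunit, had a log2 fold change of -2.51 (SE 0.361, adjusted p = 0.0317) and MELK, a kinase of dividing cells, of -2.28 (SE 0.200, adjusted p = 0.00573). PPIL1, a spliceosomal prolyl isomerase, fell from 114 ± 10.96 to 22.7 ± 1.49 CPM (log2 -2.33, SE 0.156, adjusted p = 0.00244). MLEC, which encodes the endoplasmic reticulum lectin malectin, fell by 2.23 (SE 0.229, adjusted p = 0.00917). PSD4, an exchange factor for ARF GTPases, fell by 2.17 (SE 0.306, adjusted p = 0.0290), and OMD, which encodes the proteoglycan osteomodulin, fell by 2.19 (SE 0.324, adjusted p = 0.0353). Also among the 12 were the sense intronic RNA gene ENSG00000265579 (chromosome 18, 72743756 to 72745961; log2 -3.34, SE 0.357, adjusted p = 0.00995) and ENSG00000272579, for which no annotation was used here (log2 -2.37, SE 0.2496, adjusted p = 0.00937). SLBP, BRCA2, PPIL1, MLEC and PSD4 carry TCCAAGA or CCAAGAA in a 3' untranslated region, and the first of these words also occurs in the SULT2B1 coding sequence. With the block, PPIL1 (0.0327) and H4C3 (0.0122) still passed, and the other 10 had adjusted p between 0.0535 (NCAPG2) and 0.153 (RRM2). With equal weight per cell OMD did not pass (0.0547). Of the 12 falls 5, 7 and 8 passed without control library 1, 2 or 3, and 4, 4 and 5 without knockdown library 1, 2 or 3.

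**Figure D2:**
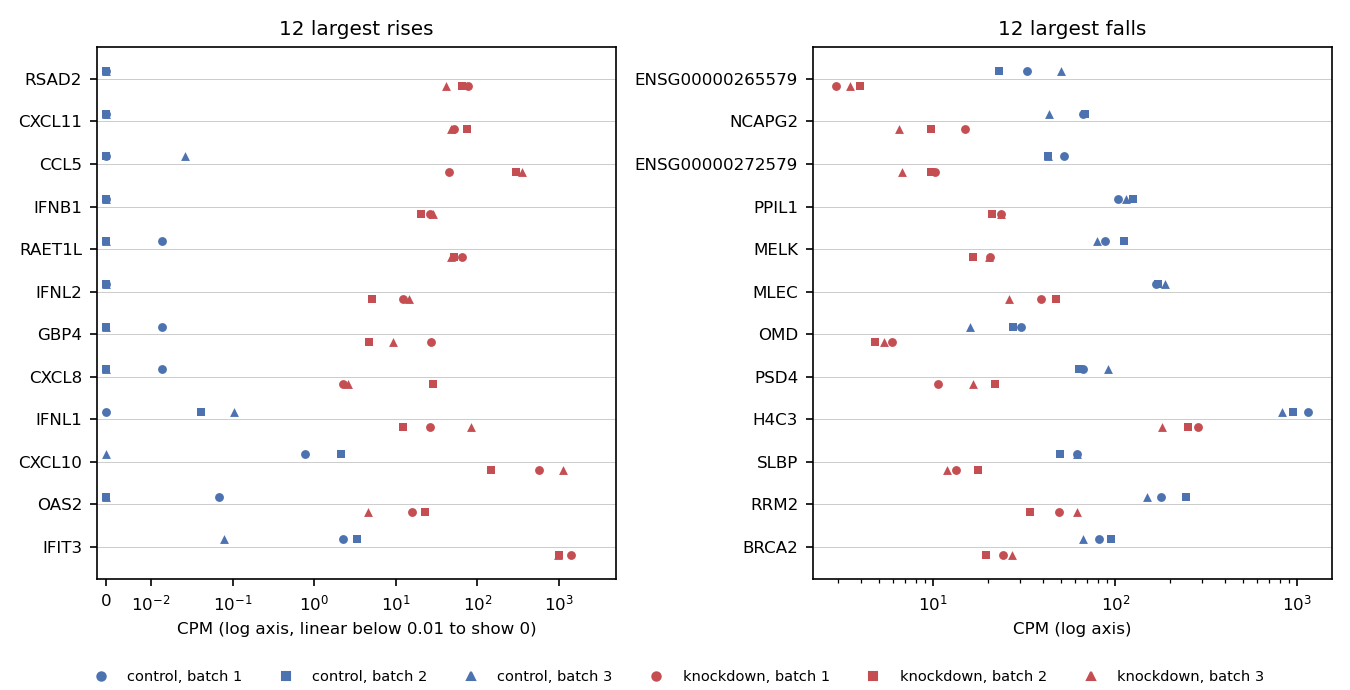
CPM (horizontal axes, log scale, linear below 0.01 in the left panel to show 0) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in each of the 3 control and 3 knockdown libraries. For each gene in the left panel the 3 knockdown libraries lie to the right of the 3 control libraries, and in the right panel to the left of them.

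Interferon response genes rose as a group (camera adjusted p = 7.12e-40). Of 36 members tested, 21 were higher in knockdown over all genes and none lower, and 32 were higher when adjusted over the list alone. IFIT2 rose from 7.09 ± 2.08 to 2024 ± 297 CPM (log2 8.16, SE 0.296), and IFIT1 from 2.98 ± 1.65 to 796 ± 151 (8.06, SE 0.530). IFI6 rose from 4.37 ± 1.11 to 165 ± 19.02 (5.24, SE 0.245) and RIGI, the cytoplasmic sensor of short double-stranded RNA, from 16.4 ± 3.07 to 372 ± 40.1 (4.51, SE 0.187). In this order their edgeR adjusted p was 0.000223, 0.00244, 0.000378 and 0.000223. MX1, another antiviral gene, chosen after its values were seen, did not pass (4.72 ± 2.89 and 5.57 ± 2.81 CPM, log2 0.24, adjusted p = 0.939). The median log2 fold change of the list was 4.01 (quartiles 1.61 and 7.11), the same with the 3 members without control reads set at their limit. The medians within batches 1, 2 and 3 were 3.07, 3.18 and 2.90 on log2(CPM + 1). The list had an adjusted p = 0.00242 with an estimated correlation, which became 0.131 when the block was added. With the block, 10 members passed, and without the cells over 20% mitochondrial reads 23 did.

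At least 1 read of IFIT2, IFIT1, IFIT3, RIGI and IFI6 was found in most knockdown cells, and of RSAD2, CXCL11, OAS2 and GBP4 in a minority. An IFIT2 read was present in 11.3% ± 3.91 of control and 95.2% ± 4.27 of knockdown cells, an IFIT1 read in 6.65% ± 1.89 and 83.7% ± 11.6, and a RIGI read in 36.4% ± 5.04 and 88.0% ± 1.28 (SD, n = 3). An IFIT3 read was present in 5.72% ± 3.87 and 84.3% ± 5.79, and an IFI6 read in 61.4% ± 13.03 and 98.5% ± 1.52. For each of the 5 the exact permutation p was 0.1, and 0.25 within batches. In knockdown, RSAD2 reads were present in 29.3% ± 9.47 of cells, CXCL11 reads in 22.3% ± 8.30, OAS2 reads in 10.8% ± 5.28 and GBP4 reads in 9.85% ± 2.03. The control shares of these 4 genes were 0%, 0%, 0.877% ± 1.52 and 0.439% ± 0.760. IFNB1 reads occurred in 0 of 76, 66 and 67 control cells, which allows, as for RSAD2 and CXCL11, shares of up to 3.95%, 4.55% and 4.48%. They occurred in 5 of 66, 6 of 65 and 9 of 61 knockdown cells. IFNL1 reads occurred in 11, 5 and 23 of those knockdown cells. A single cell held 97.5%, 83.6% and 95.2% of the IFNB1 reads of knockdown batches 1, 2 and 3. CXCL10 was detected in 1.95% ± 2.34 of control and 50.2% ± 22.2 of knockdown cells. With each cell thinned to 100000 reads the knockdown shares were 69.2% for IFIT2, 58.8% for IFIT1, 51.5% for IFIT3, 68.5% for RIGI and 86.9% for IFI6, against 8.39%, 3.83%, 3.84%, 24.4% and 24.97% in control. They were 20.5% for CXCL10, 17.3% for RSAD2, 10.4% for CXCL11, 7.75% for OAS2, 7.78% for GBP4, 4.73% for IFNB1 and 11.6% for IFNL1. With a minimum of 5 reads in unthinned cells the IFIT3 share was 49.95% and the CXCL10 share 22.6%.

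Genes of the TNF and NF-kB response were also higher in knockdown (camera adjusted p = 3.75e-11, and adjusted p = 0.0186 with an estimated correlation, or 0.305 with the block as well). Of 28 members 5  rose over all genes and 13 adjusted over the list alone, with none lower. NFKBIA, the inhibitor that NF-kB induces, rose from 36.9 ± 4.77 to 117 ± 3.61 CPM (log2 1.67, SE 0.153, edgeR adjusted p = 0.00573). BIRC3, an inhibitor of apoptosis that binds TNF receptor complexes, rose from 11.9 ± 4.45 to 211 ± 64.0 (4.15, SE 0.378, adjusted p = 0.00600) and NFKBIZ, a nuclear regulator of the same pathway, from 4.51 ± 1.34 to 43.2 ± 15.5 (3.26, SE 0.371, adjusted p = 0.0127). CXCL10 and CXCL8 were the others. The list's median log2 fold change was 1.16 (1.13, 1.07 and 0.767 within batches 1, 2 and 3). BIRC3 alone of the 5 passed with the block. TNF itself, chosen after its values were seen, had 0 reads in every control library and 144, 0 and 42 in the knockdown libraries, from 3, 0 and 2 cells.

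Among 23 p53 targets 3 rose over all genes and 16 adjusted over the list alone. FAS, the receptor for FAS ligand, rose from 24.7 ± 0.828 to 101 ± 5.91 CPM (log2 2.03, SE 0.146, edgeR adjusted p = 0.00263). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 46.5 ± 3.01 to 149.99 ± 15.9 (1.69, SE 0.139, adjusted p = 0.00391) and RRM2B, the p53-induced ribonucleotide reductase subunit, by 0.85 (adjusted p = 0.0401; 0.152 with the block). The list's median was 0.89 (0.926, 0.920 and 0.571 within batches), camera adjusted p = 3.93e-11, but adjusted p = 0.0752 with an estimated correlation. In the death receptor list 2 of 34 members, FAS and BIRC3, rose over all genes and 4 adjusted over the list alone. CASP8, the initiator caspase of this pathway, had 46.1 ± 7.41 and 80.1 ± 10.2 CPM (log2 0.80, adjusted p = 0.114). That list's median was 0.43 (0.339, 0.439 and 0.307 within batches), with camera adjusted p = 0.000129 and adjusted p = 0.0752 with an estimated correlation. Of 21 BCL2 family genes, PMAIP1, which encodes the pro-apoptotic protein NOXA, rose over all genes (log2 2.52, adjusted p = 0.0400, and 0.0327 with the block). Adjusted over the list alone, 1 member rose and 1 fell. The median was 0.50, camera adjusted p = 0.0152, and adjusted p = 0.120 with an estimated correlation. A FAS read was present in 30.7% ± 7.01 of control and 72.6% ± 6.86 of knockdown cells, and a BIRC3 read in 27.0% ± 4.05 and 89.0% ± 1.67 (SD, n = 3; exact permutation p = 0.1 for both). Thinned, these shares were 23.6% and 57.4% for FAS and 14.8% and 71.8% for BIRC3. Without the cells over 20% mitochondrial reads, 4 NF-kB genes, 3 p53 targets and 2 death receptor genes rose, and PMAIP1 did not pass.

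Genes of S phase and of G2 and M phase were lower in knockdown (camera adjusted p = 1.69e-16 and 4.31e-17), though not past the threshold with an estimated correlation (adjusted p = 0.115 and 0.383). Of 42 S phase genes, SLBP, RRM2 and USP1 fell over all genes, none rose, and 28 fell adjusted over the list alone. USP1, a deubiquitinase of DNA repair proteins, fell from 125 ± 18.2 to 55.4 ± 5.995 CPM (log2 -1.17, edgeR adjusted p = 0.0276, and 0.0690 with the block), and carries CCAAGAA in a 3' untranslated region. The median was -0.89 (-1.01, -1.21 and -0.422 within batches 1, 2 and 3), and none of the 3 passed with the block. Of 53 G2 and M phase genes none passed over all genes and 26 fell adjusted over the list alone. NUSAP1, a spindle protein gene, had 349 ± 129 and 98.7 ± 41.5 CPM (log2 -1.82, adjusted p = 0.0836), and MKI67, the proliferation marker Ki-67, 110 ± 28.4 and 31.1 ± 16.5 (log2 -1.83, adjusted p = 0.108). That list's median was -1.31 (-0.773, -2.53 and -0.658 within batches 1, 2 and 3), and fry gave it an adjusted p of 0.136. Its median difference of log2 CPM was -1.37, and -0.76 without batch 2. An MKI67 read was found in 73.5% ± 6.15 of control and 42.8% ± 5.40 of knockdown cells (SD, n = 3; exact permutation p = 0.1), and in 58.6% and 27.2% when thinned. Without the cells over 20% mitochondrial reads 4 S phase genes and no G2 and M phase gene fell over all genes.

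Androgen response genes were lower by camera (adjusted p = 2.63e-06), with adjusted p = 0.0752 with an estimated correlation. Of 31 members 3 fell over all genes, none rose, and 11 fell adjusted over the list alone. KLK3, which encodes prostate-specific antigen, fell from 798 ± 200.03 to 280.4 ± 71.0 CPM (log2 -1.51, SE 0.233, edgeR adjusted p = 0.0416). Its neighbour KLK2 fell from 109 ± 16.9 to 45.6 ± 8.57 (log2 -1.26, adjusted p = 0.0446) and MPHOSPH9 from 141 ± 15.2 to 67.9 ± 6.58 (log2 -1.06, adjusted p = 0.0232). None of the 3 passed with the block (0.154, 0.0703 and 0.140), and KLK2 did not pass with equal weight per cell (0.0513) or without the cells sequenced again (0.0534). The list's median was -0.74 (-0.987, -0.578 and -0.703 within batches). Among the 13 members searched whose 3' untranslated region lacks CCAAGA, which TCCAAGA and CCAAGAA share, the median was -0.54. KLK3 carries CCAAGA, and KLK2 and MPHOSPH9 do not. Without the cells over 20% mitochondrial reads 4 members fell. KLK3 was also the only member of the 13 luminal epithelial markers to pass over all genes, a list with a camera adjusted p of 0.308. Adjusted over that list alone, 3 members rose and 1 fell. The luminal keratins KRT18 and KRT8 were at log2 0.61 and 0.81 (adjusted p = 0.0641 and 0.0930).

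**Figure D3:**
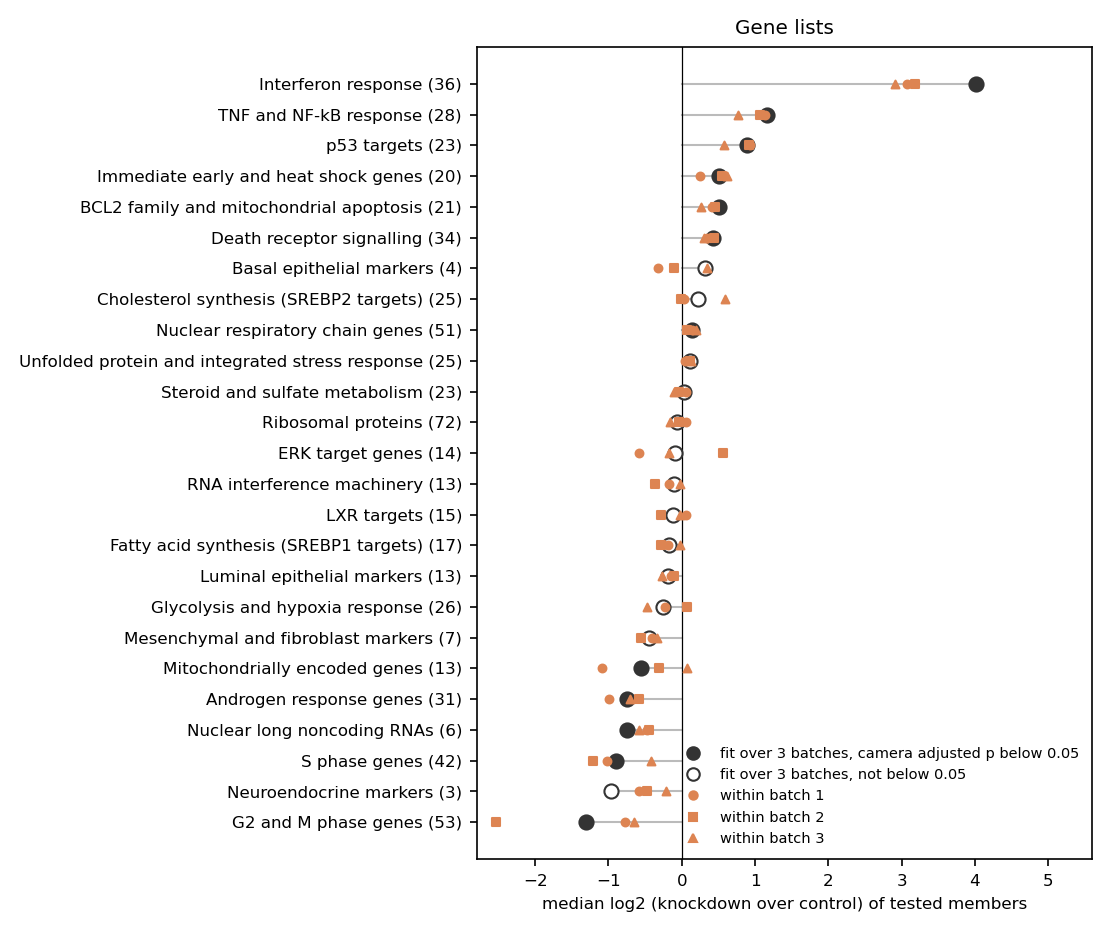
Median log2 (knockdown over control) of the tested members of 25 gene lists (horizontal axis; number tested in parentheses), from the fit over 3 batches (circles, filled where the camera adjusted p was below 0.05) and within each batch on log2(CPM + 1) (small symbols). The interferon response lies farthest to the right at 4.01 and the G2 and M phase genes farthest to the left at -1.31.

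In 4 further lists camera gave an adjusted p below 0.05 that did not hold with an estimated correlation. Immediate early and heat shock genes were higher (20 tested, 1 called, the chaperone gene DNAJA1 at log2 0.74 with edgeR adjusted p = 0.0362, and 0.0977 with the block; list median 0.50, camera adjusted p = 0.000751, and adjusted p = 0.115 with an estimated correlation). Nuclear-encoded respiratory chain genes were higher by a small amount (51 tested, 0 called; median 0.14, camera adjusted p = 0.0162, and 0.654 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -0.55 (-1.08, -0.309 and 0.0770 within batches 1, 2 and 3; camera adjusted p = 0.0265, and 0.654 with an estimated correlation). For the 6 tested members of the list named nuclear long noncoding RNAs, the median was -0.75 (camera adjusted p = 0.0162, and 0.140 with an estimated correlation). Where these RNAs lie in the cell was not measured. Adjusted over the list alone 4 of them were lower, among them GAS5 (707 ± 45.5 and 450.2 ± 42.7 CPM, adjusted p = 0.0517 over all genes). Without the cells over 20% mitochondrial reads the camera adjusted p of the mitochondrial, noncoding and respiratory chain lists was 0.983, 0.0903 and 0.0754, and that of the glycolysis list fell to 0.0265. In all, 12 of 25 lists passed with camera, 7 higher and 5 lower, and 2 with an estimated correlation.

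Lipid and steroid genes, the pathways nearest to the enzymatic role of SULT2B1, showed no list below 0.05 in the main test with camera. The 25 cholesterol synthesis genes had a median log2 of 0.22 (camera adjusted p = 0.0593), and of 0.0250, -0.00616 and 0.589 within batches 1, 2 and 3. The 17 fatty acid synthesis genes had a median of -0.18 (0.178), with ACLY, which makes cytosolic acetyl-CoA, at 434 ± 53.9 and 267 ± 6.31 CPM (adjusted p = 0.0517). LXR targets (15 tested, 0.896) and steroid and sulfate metabolism genes (23 tested, 0.774) did not pass. Nor did glycolysis and hypoxia genes (26 tested, 0.0905), ribosomal proteins (72 tested, 0.139), the unfolded protein and integrated stress response (25 tested, 0.305), the RNA interference machinery (13 tested, 0.338) or ERK target genes (14 tested, 0.896). RPL32 was the ribosomal gene that fell (407 ± 54.7 to 166 ± 19.5 CPM, log2 -1.29, adjusted p = 0.0114), together with its pseudogene RPL32P18, with which it may share reads. Among markers of other cell types, mesenchymal (7 tested, 0.375), neuroendocrine (3 tested, 0.375) and basal markers (4 tested, 0.931) did not pass. Of the blood and endothelial markers VWF alone passed the filter on low counts, with 1183 control and 1010 knockdown reads. Median, mean and test differed in sign for the basal, ERK, LXR and steroid lists, whose members went both ways.

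Scored per cell, these groups had the same direction in each batch. The mean interferon score (mean log2(CPM + 1) over the list) was 1.19 ± 0.0850 in control and 2.99 ± 0.133 in knockdown (SD, n = 3), and the SD between cells of a batch was 0.381 ± 0.0866 and 1.53 ± 0.0860. Of the knockdown cells, 55 of 66, 53 of 65 and 48 of 61 scored above every control cell of their batch. Mean scores were higher in knockdown for the NF-kB list (1.02 ± 0.0271 and 1.75 ± 0.0504), p53 targets (2.82 ± 0.193 and 3.93 ± 0.0395) and death receptor genes (1.81 ± 0.0664 and 2.34 ± 0.0565). They were lower for androgen response genes (4.10 ± 0.113 and 3.54 ± 0.178), S phase genes (3.16 ± 0.379 and 2.29 ± 0.130) and G2 and M phase genes (3.83 ± 0.750 and 2.36 ± 0.305). The G2 and M phase difference was -1.47, and -0.90 without batch 2. Each of these differences over all batches had an exact permutation p of 0.1, the smallest possible, and 0.25 within batches. Adjusted over the 25 lists scored, the p was 0.192.

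**Figure D4:**
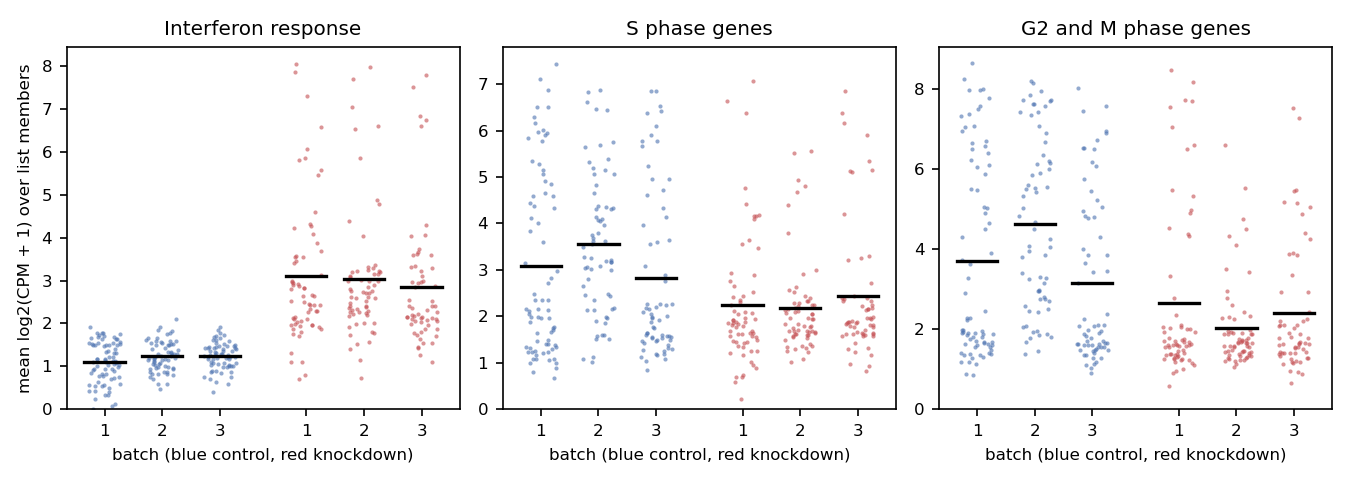
Per-cell list scores (mean log2(CPM + 1) over the list's members, vertical axis) of single cells (points) in each control and knockdown batch for the interferon, S phase and G2 and M phase lists, with batch means as bars. Interferon scores average 1.19 in control and 2.99 in knockdown batches, where they also spread more widely between cells.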

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

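The settings that leave out cells over 20% mitochondrial reads, require a read in 10% of cells, or join the estimated correlation with the block or with the first of these were chosen only after the results were seen. All 158 genes kept their direction in every setting that tested them, and none of the named genes reversed. Of the 41 named genes called, 39 passed without a filter on low counts, 39 without cells over 20% mitochondrial reads, 38 with equal weight per cell, 17 with the block, 18 to 24 with 1 library left out and 4 to 8 with 1 batch left out (0 of the 12 largest falls). The number of genes called was 158 with RLE size factors, 150 without the cells sequenced again and 198 without cells over 20% mitochondrial reads, but 1442 with DESeq2, 309 without a filter on low counts, 428 with each cell thinned to 100000 reads, 293 with a read in at least 10% of cells and 242 with equal weight per cell. With batch as a replicate block it was 38 (37 of the 158 among them), and 88 with the block and equal weight; fewer degrees of freedom are part of that fit's construction. Leaving out replicates gave 5 to 69 genes, with fewer libraries in the fit: 69, 68 and 65 without control library 1, 2 or 3, 46, 48 and 63 without knockdown library 1, 2 or 3, and 7, 5 and 11 without batch 1, 2 or 3 in both arms. SULT2B1 passed with DESeq2 (log2 -4.14) and in no other setting; its log2 fold change was -3.54 to -4.99 with 1 library left out, -2.99 to -5.26 with 1 batch left out and -1.48 with equal weight per cell, on log2(CPM + 1). The filter on cells removed 0 cells and tests nothing.

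The number of lists past the threshold was 12 with camera and with the block, 9 with fry and 13 with equal weight per cell. It was 2 with an estimated correlation (also without cells over 20% mitochondrial reads), 0 with the block and an estimated correlation, and 8 to 13 with replicates left out. Where 13 passed, a list outside the 12 was among them. Adjusted p with an estimated correlation, then with the block added, then without cells over 20% mitochondrial reads, were 0.0752, 0.342 and 0.0652 for androgen response genes and for p53 targets, 0.0752, 0.342 and 0.0715 for death receptor genes, 0.115, 0.342 and 0.113 for S phase genes, and 0.383, 0.583 and 0.401 for G2 and M phase genes, which fry put at 0.136. With the block and an estimated correlation the interferon list was at 0.131 and the NF-kB list at 0.305. Of lists that did not pass, direction reversed for ERK targets when cells were thinned (0.920) or weighed equally (0.953), and with replicates left out for ERK targets (adjusted p 0.481 to 0.958), basal markers (0.630 to 0.939), LXR targets (0.572 to 0.922) and steroid genes (0.596 to 0.958). The difference in mitochondrial share between the arms reversed from the median to the mean over cells (-3.43 percentage points); for these reversals, the lost list calls and the larger counts the cause was not tested. The SULT2B1 values rest on 34 reads in the knockdown arm and 593 in control.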

Other observations

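The tests of mitochondrial share against the interferon genes, and of single batches and of seed sites against the cell cycle genes, were chosen only after the result was seen. Outside the 26 lists lay 49 of the 80 genes that rose and 71 of the 78 that fell. Examples given here from both sets were chosen after their values were seen. Among the rises, B2M, the invariant chain of class I molecules, went from 848 ± 62.7 to 1722 ± 202 CPM (log2 1.02, SE 0.115, edgeR adjusted p = 0.0126). PSMB9, an immunoproteasome subunit, went from 0.897 ± 0.404 to 13.5 ± 2.99 CPM (log2 3.91, adjusted p = 0.0155). PSME1 and TAPBP, a proteasome activator and the peptide-loading factor tapasin, rose by 0.77 and 0.87 on the log2 scale (adjusted p = 0.0378 and 0.0410). GBP1, a guanylate-binding protein gene, rose by 4.74 (adjusted p = 0.00995), and SAMHD1, which degrades deoxynucleotides, by 1.41 (adjusted p = 0.0470). SQSTM1 and OPTN, receptors of selective autophagy, rose by 1.21 and 2.62 (adjusted p = 0.0470 and 0.0127). With batch as a block B2M still passed (0.0327), and the other 7 were between 0.0535 (GBP1) and 0.117.

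Among the falls outside the lists, DDX21, a nucleolar helicase, went from 531 ± 10.99 to 268 ± 13.8 CPM (log2 -0.99, edgeR adjusted p = 0.00632). NCL, which encodes nucleolin, went from 578 ± 52.9 to 256 ± 42.8 (log2 -1.18, adjusted p = 0.0175), and NPM1, nucleophosmin, from 666 ± 55.2 to 345 ± 29.5 (log2 -0.95, adjusted p = 0.0145). The pseudogenes NPM1P27 and NPM1P6, nearly identical to NPM1 in sequence, passed as well, so reads of these genes are uncertain. NHP2, a protein of small nucleolar ribonucleoproteins, fell by 1.56 (adjusted p = 0.00863). CTNNA1, which encodes alpha-catenin, fell by 1.25 (adjusted p = 0.00744), and the desmosomal cadherin gene DSG2 fell by 1.15 (adjusted p = 0.0175). PLPP1, a lipid phosphatase, went from 279 ± 13.9 to 87.4 ± 4.55 CPM (log2 -1.67, adjusted p = 0.00244) and SLC39A6, a zinc transporter, from 295 ± 3.89 to 104 ± 9.30 (log2 -1.51, adjusted p = 0.00263). DDX21, NCL, NHP2, CTNNA1 and SLC39A6 carry TCCAAGA or CCAAGAA in a 3' untranslated region, and NPM1, DSG2 and PLPP1 do not. With batch as a block DDX21 (0.0477), PLPP1 (0.0267) and SLC39A6 (0.0327) still passed, and the other 5 named here were between 0.0535 (NHP2) and 0.117 (NCL).

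The rise of interferon response genes is not accounted for by the control cells of high mitochondrial share, since 23 members still rose without cells over 20% mitochondrial reads. Detection of IFIT2 was not confined to a few cells, as the lowest share of knockdown cells with its read in any batch was 91.8%. RSAD2, CXCL11, OAS2 and GBP4 reads were in 9.85% to 29.3% of knockdown cells. With cells thinned to 100000 reads the shares were 69.2% for IFIT2 and 7.75% to 17.3% for these 4. Such shares do not show how reads are spread over cells, so whether a minority held most IFIT2 reads stays open. By the interferon score, 83.3%, 81.5% and 78.7% of knockdown cells of batches 1, 2 and 3 lay above every control cell of their batch. The loss of SULT2B1 and the siRNA itself cannot be told apart as sources of the interferon rise. The control siRNA came from another supplier, and the knockdown cells that still held a SULT2B1 read, 4 in all, were too few to compare. Sensing of the transfected double-stranded RNA is a candidate explanation that was not tested, and the loss of SULT2B1 stays open beside it. RIGI and IFNB1 rose, but RIGI is itself a member of the interferon list, so its rise is part of what is to be explained. Control cells were transfected with an siRNA as well, and an IFNB1 read was found in 0% of them. A second SULT2B1 siRNA or a control of the same chemistry would be needed and was not analysed here.

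The lower S phase and G2 and M phase genes were not explained by the cells of high mitochondrial share, since the median differences of log2 CPM were -0.90 and -1.44 without them. A single batch does not account for the S phase fall, whose median nearest to 0 with 1 batch left out was -0.82 (-0.91 over all), but for G2 and M phase that median was -0.76, without batch 2, against -1.37 over all, so how far batch 2 carries it stays open. Seed sites in the members' own 3' untranslated regions do not account for these falls either. Among members searched and without a site the medians were -0.87 for S phase (28 genes) and -1.31 for G2 and M phase (40 genes). Whether sites in other genes lowered these members indirectly was not tested. For the G2 and M phase list, setting control libraries 1 and 2 with knockdown library 1 against the rest gave a camera adjusted p of 8.57e-29. This was smaller than that of the real split (4.31e-17). A slower cell cycle in knockdown cells is a hypothesis that these counts leave open, with the siRNA and the loss of SULT2B1 again inseparable; DNA content or growth of the cells would be needed and was not analysed here.

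Genes that were lower in knockdown cells carried a shared short word in their 3' untranslated regions more often than other genes. Of 16065 words of 7 bases in 9071 genes, TCCAAGA went with the lowest values (Bonferroni p = 9.30e-19; median log2 -0.20 in 1220 genes and 0.01 in the others), it ranked 1, 1 and 2 within batches 1, 2 and 3, and 0 words passed in the other direction or after shuffling. Medians were graded by site, at -0.25 for TCCAAGAA (485 genes), -0.16 for the other TCCAAGA sites (735 genes) and -0.10 for CCAAGAA (914 genes). They were -0.02 for CCAAGA (1457 genes) and 0.04 without any of these (5480 genes). Unlike the scan, these medians were not adjusted for the length of the regions. Its median log2 was 11.8, 11.7, 11.5, 11.3 and 9.92 in the same order, so length and site go together here. The site classes were also built on the word picked in the scan. Of the 71 genes that fell and could be searched, 46 had a site of at least 7 bases. From the length and composition of their regions 17.9 ± 3.35 (SD) were expected. The word was picked on genes that include these 71, and the expected number does not allow for that, so the excess restates the scan. The word lies in the coding sequence of both SULT2B1 coding transcripts. It spans chromosome 19, 48591663 to 48591669, in exon 4 of 7 in SULT2B1-201 and exon 3 of 6 in SULT2B1-202. Of all words of 7 bases, 9.21% occur somewhere in either transcript, untranslated regions included. Off-target repression by an siRNA guide with the seed TCTTGGA could give such a pattern, but was not tested. The siRNA sequence was not used here, and a cellular small RNA with the same seed was not tested; SLBP, BRCA2, PPIL1, MLEC and PSD4 had such a site, while NCAPG2, MELK, OMD, H4C3 and RRM2 had none.

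The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, gave as many as 158 calls with edgeR, and the highest of the others gave 0. At an unadjusted p of 0.05 the real split had 2739 genes and the others between 575 and 882. For lists, 1 split, the real one, gave as many as 12, and the highest of the others gave 9. Each of the other 9 splits sets 2 libraries of an arm and 1 of the other against the rest, so differences between the arms do not cancel in it. With the preset correlation the interferon list passed in all 9 (adjusted p 0.000820 to 0.00790), G2 and M phase genes in 7 (lowest 8.57e-29), S phase genes in 5 (lowest 3.50e-09), p53 targets in 5 (lowest 0.000253), and NF-kB and androgen response genes in 3 each (lowest 0.00836 and 0.00966). Among the 4 splits that part all 3 pairs of same-numbered libraries, the real one included, the others gave between 4 and 7 lists and 0 genes. With an estimated correlation the real split gave 2 lists and the others 0.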
